A study of Mus musculus with 6 samples.

How the data were processed

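Polyadenylated RNA of 2H11 cells was sequenced from 6 samples, 3 untreated and 3 treated with BMP4 for 48 h. Per the labels' protocols, strand-specific libraries were made with a Roche KAPA kit and read as paired ends on an Illumina HiSeq. Per the submitters' processing notes, FastQC, cutadapt, HISAT2 and StringTie were used on the mouse build GRCm38; their versions, settings and annotation release are not given in the sources used here. The deposited values are FPKM per gene and FPKM per transcript, per the file headers, in 2 tables with coordinates. The genes listed were 11754, all protein-coding, and the higher of the 2 group means was at least 0.502 FPKM in each, so the deposited list was filtered at about that level and genes low in both groups are outside it. Each table held 1 emptied line, which was skipped.

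The tables were checked before use. For the 1147 genes whose transcripts in GENCODE M21 were all listed, the deposited gene FPKM equalled the length-weighted sum of transcript FPKM over the exonic length of the gene within 1% in 100% of values. Low values of genes with a single transcript were searched for steps of whole reads: at the best step size, 21.0% to 26.0% of the 100 lowest values per sample fell within 0.05 of a step of a whole multiple, against 17.0% to 22.0% of random values in the same range. No step was found, so the depth per sample could not be recovered, and the precision of each value is known only from the 3 replicates. No 2 samples were identical (0 pairs). GENCODE M21, which is on the same build, held 99.8% of the gene identifiers without their version and 87.2% of the transcript identifiers with it; it was used for exonic length, GC content and exon overlap only. Coordinates are those of the deposited tables.

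From the FPKM values, log2(FPKM + 1) was computed and genes or transcripts with a mean of at least 1 FPKM over the 6 samples were tested, 10932 genes and 17213 transcripts; 822 genes lay below. BMP4 was compared with untreated by limma 3.58.1 in R 4.3.3 (moderated two-sided test, variance trend with intensity), with Benjamini-Hochberg adjustment and a threshold of 0.05. An adjusted p called a limma adjusted p in the text is from this test of a gene or transcript. No covariate was used. A count test was planned in case the tables held read counts; they hold FPKM, so the planned test for FPKM was used and the count-based alternatives were not run. Unequal change of the transcripts of a gene was tested with limma's diffSplice (Simes test per gene). Gene lists with at least 5 tested members were tested against all other tested genes with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. With an estimated correlation camera also takes its degrees of freedom from the 6 samples, not from the number of genes. Its p-values can therefore rise even where the genes of a list are not correlated. Fry, which asks whether the genes of a list change and compares them with no other genes, was run on the same lists.

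The 26 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls by log2 fold change among genes past the threshold whose groups did not overlap, leaving out predicted or clone-named genes. It added up to 4 tested members of each list in order of adjusted p, 13 genes of interest (Id1, Smad6, Runx2, Sp7, Alpl, Bglap, Ibsp, Spp1, Pecam1, Cdh5, Kdr, Tek and Rarb), and the 3 genes with the smallest p in the transcript-share test. Further list members are named in the text where few members moved against their list or did not pass; these were chosen after their values were seen. Members of a list without a value were not analysed here. Genes that share reads with a close copy, such as Ifit3 and Ifit3b, Bglap and Bglap2, H2-K1 and H2-D1, or Hspa1a and Hspa1b, are uncertain, since the handling of multiply mapped reads is not given in the sources used here.

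Each test was checked on simulated data drawn from the means and spreads of the deposited values. In the gene comparison (10932 genes, 200 of them changed), 85.1% of changes of 0.5 on the log2 scale, 97.0% of changes of 1 and 98.5% of changes of 2 were recovered, with 13 false calls. In a simulation of 23 lists of 20 genes with 1 shifted by 0.5, camera found that list and called 0 of the others. The simulated genes were drawn independently of each other, so this does not check camera where the genes of a list are correlated. In the deposited values the estimated correlation within a list reached 0.701, for mitochondrially encoded genes. In the transcript comparison (17213 transcripts), 37.0% of changes of 1 and 68.0% of changes of 2 were recovered with 7 false calls. In the transcript-share test (3871 genes), diffSplice recovered 32.0% and 72.0% with 36 false calls. A test with a spread per transcript was therefore added, in which each transcript minus the mean of the other transcripts of its gene entered limma with a Simes test per gene; it recovered 9.00% and 46.0% with 7 false calls.

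Alternatives were pseudocounts of 0.1 and 0.01, no filter, means of at least 0.1 or 5, scaling by trimmed means of log ratios, quantile normalization, rescaling to equal sums (TPM), robust variance estimation, the replicate number as a block, and leaving out each sample in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the reference annotation and the plots.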

Results

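RNA abundance was measured in 2H11 cells, an established mouse line that the labels call endothelial and whose source they give as axillary lymph node and vascular epithelium of the C3H/HeJ strain. The cells were starved and then cultured for 48 h without or with BMP4, a secreted bone morphogenetic protein that signals through the transcription factors SMAD1, SMAD5 and SMAD9. Each of the 2 groups had 3 samples, and for each sample the deposited values were FPKM (fragments per kilobase, relative to the size of the library) of 11754 protein-coding genes and of 22148 transcripts. The sum of FPKM over the genes was 256997 to 273562 in the untreated samples and 252329 to 264273 in the BMP4 samples. These sums do not give the number of reads, so the depth behind each value is unknown and no counting interval is given. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples. Across genes, log2(FPKM + 1) correlated within groups at r = 0.988 to 0.993 and between groups at r = 0.964 to 0.970, and the first principal component, which parted the groups, held 68.2% of the variance.

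The first comparison asked which genes differ between 2H11 cells kept with BMP4 and those kept without it. Secreted BMP antagonists were among the genes that rose most: noggin (Nog) went from 0.202 ± 0.142 to 29.0 ± 1.70 FPKM (SD, n = 3 per group) and gremlin 1 (Grem1) from 14.7 ± 0.208 to 117 ± 0.102. On the log2(FPKM + 1) scale the genes that fell most were Mest, an imprinted gene, from 28.2 ± 1.79 to 1.54 ± 0.0937 FPKM, and Msln, which encodes the surface protein mesothelin, from 14.3 ± 1.44 to 0.506 ± 0.0914. With limma's moderated test, 3046 of 10932 tested genes changed, of which 1487 were higher and 1559 lower with BMP4. An absolute log2 fold change of at least 1 was reached by 315 of them, 151 higher and 164 lower, and by 191 with a stricter filter, a mean of at least 5 FPKM, where fewer genes are tested. All BMP4 samples lay on one side of all untreated samples for 4978 genes, or 45.5% of those tested, where chance gives 10%. Without BMP4 replicate 1 the number of genes higher with BMP4 was 985.

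Among the 12 largest rises by log2 fold change, the first was Nog (chromosome 11, 89300638 to 89302332, GRCm38) at 4.65 (SE 0.10, limma adjusted p = 6.64e-07). Next came the transcriptional repressor Hey1 (chromosome 3, 8663359 to 8667256) at 3.71 (SE 0.07), whose mean rose from 0.0877 ± 0.0185 to 13.2 ± 0.635 FPKM. Cck, the gene of the peptide hormone cholecystokinin, rose from 1.68 ± 0.284 to 29.9 ± 3.38 FPKM, a 17.7-fold ratio of the means. F13a1, which encodes the A subunit of a clotting factor, rose from 0.132 ± 0.0720 to 11 ± 0.465 FPKM. Rgs4, a regulator of G protein signalling, and Draxin, an axon guidance protein, rose by log2 fold changes of 2.89 and 2.81. Id4, a dominant negative partner of helix-loop-helix factors, rose by 2.76, the matrix protein gene Tnc (tenascin C) by 2.68, Ctgf (connective tissue growth factor) by 2.66 and Rarres1 by 2.53. The limma adjusted p of these genes, Grem1 included, lay between 1.5e-07 for Grem1 and 1.11e-05 for Rarres1.

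Among the 12 largest falls, Mest (chromosome 6, 30723547 to 30748465) had a log2 fold change of -3.52 (SE 0.07, limma adjusted p = 6.64e-07), an 18.2-fold lower mean. Msln (chromosome 17, 25748614 to 25754327) had -3.35 (SE 0.09, limma adjusted p = 1.39e-06). Tnnc1, the troponin C of slow and cardiac muscle, fell from 18.7 ± 1.16 to 1.41 ± 0.132 FPKM and the tight junction gene Cldn15 from 12 ± 1.08 to 0.609 ± 0.209. Dpt, which encodes the matrix protein dermatopontin, fell from 245 ± 17 to 41.1 ± 3.37 FPKM, and Angptl4, an inhibitor of lipoprotein lipase, from 50.0 ± 2.38 to 8.84 ± 0.442. Apod (apolipoprotein D) fell by 2.35 on the log2 scale and the urea transporter gene Slc14a1 fell by 2.17. By the ratio of means Apod was 29.1-fold, Msln 28.3-fold, Slc14a1 21.2-fold and Cldn15 19.7-fold lower, each more than Mest. The remaining genes of the 12 were Zbp1, Ifit3, Rsad2 and Ifit3b, which belong to the interferon response, with log2 fold changes of -2.68, -2.20, -2.19 and -2.16. Ifit3 and Ifit3b are near-identical neighbours, so the division of reads between them is uncertain. The log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near 0.

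**Figure D1:**
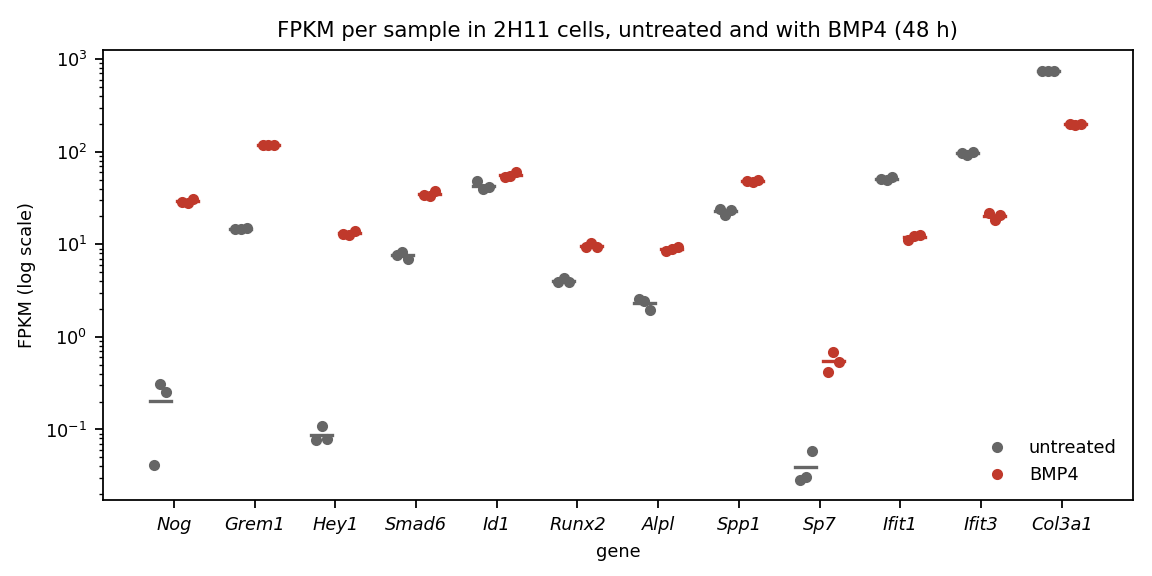
FPKM per sample on a log scale for 12 genes in 2H11 cells, with the 3 untreated samples in grey and the 3 BMP4 samples in red; each dot is a sample and each bar the mean of its group. Nog, Grem1, Hey1, Smad6, Id1, Runx2, Alpl, Spp1 and Sp7 lie higher in every BMP4 sample than in every untreated sample, and Ifit1, Ifit3 and Col3a1 lie lower, with Id1 the closest pair of groups (43.0 and 56.0 FPKM).

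Targets of BMP-SMAD signalling rose almost throughout. Of 20 tested genes of that list, 18 rose, Tbx3 fell by 0.26 on the log2 scale and Smurf1 did not pass (log2 fold change 0.12); adjusted over the list alone the counts were also 18 and 1. Tbx3 and Smurf1, like other list members outside the rule for named genes that are named below because few genes moved their way, were chosen after their values were seen. The call of Tbx3 was lost without any 1 of untreated replicates 2 and 3 (limma adjusted p = 0.0667 and 0.0760) and BMP4 replicates 1, 2 and 3 (0.0541, 0.103 and 0.0609), and with rescaling to equal sums (0.0628). Smad6, which encodes an inhibitory SMAD, rose from 7.60 ± 0.659 to 34.9 ± 2.06 FPKM (limma adjusted p = 3.29e-06). Id1, a direct BMP target, was high already in untreated cells and rose from 43.0 ± 4.47 to 56.0 ± 3.38 FPKM (log2 fold change 0.38, SE 0.08, limma adjusted p = 0.0132). The median log2 fold change of the list was 1.86, and camera with a preset correlation of 0.01 placed it above the other genes (adjusted p = 1.42e-16). The adjusted p was 0.0833 with an estimated correlation. Of 18 tested BMP ligands, receptors and SMADs, 5 rose (Fstl1, Smad1, Acvr1, Bmpr1a and Bmpr2) and 6 fell, or 8 and 6 adjusted over the list alone, and the list had no shift (camera adjusted p = 0.969). Bmper, a secreted BMP-binding protein, fell by 1.01, the protease gene Bmp1 by 0.48 and the co-receptor gene Rgma by 0.67 on the log2 scale, while Fstl1 rose from 302 ± 2.25 to 393 ± 3.84 FPKM. Without BMP4 replicate 1 or BMP4 replicate 2 the number that rose was 3, as Bmpr1a (limma adjusted p = 0.0557 and 0.0546) and Bmpr2 (0.0629 and 0.0638) no longer passed. The direction camera gave this list turned without BMP4 replicate 3 (adjusted p = 0.838; 0.698 to 0.992 over its alternatives).

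BMP4-treated endothelial cells have been studied for a turn towards bone-forming cells, and the osteoblast list addresses that question. Runx2, the transcription factor of early osteoblasts (chromosome 17, 44495987 to 44814797), rose from 4.04 ± 0.252 to 9.61 ± 0.600 FPKM (log2 fold change 1.07, SE 0.07, limma adjusted p = 5.04e-05). Alpl, the alkaline phosphatase of mineralizing cells, rose 3.80-fold from 2.33 ± 0.338 to 8.88 ± 0.459 FPKM (limma adjusted p = 2.63e-05), and Spp1 (osteopontin) from 22.7 ± 1.70 to 48.2 ± 1.11 (limma adjusted p = 2.79e-05). Ank, a pyrophosphate transporter gene, and Pth1r, the parathyroid hormone receptor gene, each rose by a log2 fold change of 1.48. Bglap (osteocalcin) rose from 0.862 ± 0.267 to 1.65 ± 0.128 FPKM (limma adjusted p = 0.0148), a call lost without BMP4 replicate 1 (limma adjusted p = 0.0546) or without BMP4 replicate 2 (0.0544), and the close paralog Bglap2 makes its reads uncertain. Sp7 (osterix) was at 0.0285, 0.0303 and 0.0587 FPKM in untreated cells and at 0.416, 0.689 and 0.540 with BMP4, below the mean of 1 set for testing. Ibsp was not analysed here.

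Over the 17 tested osteoblast genes, 9 rose and 5 fell, or 9 and 6 adjusted over the list alone. The genes that fell, named after their values were seen, were the collagen genes Col1a1 (from 1059 ± 21.6 to 691 ± 19.2 FPKM) and Col1a2, the phosphatase gene Phospho1, Omd (osteomodulin) and Tnfrsf11b, the decoy receptor osteoprotegerin. The list did not pass as a group (camera adjusted p = 0.0607 with the preset correlation and adjusted p = 0.176 with an estimated correlation). With a lower expression filter, a mean of at least 0.1 FPKM, its camera adjusted p was 0.0141, and without untreated replicate 3 or BMP4 replicate 3 it was 0.0461 or 0.0484; over its alternatives it ranged from 0.0141 to 0.176.

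Of the 30 genes of the endothelial list, 22 were not analysed here, among them Pecam1, Cdh5, Kdr and Tek. In the 7 tested, Cd34, a surface marker of vessels and progenitor cells, fell from 52.2 ± 2.83 to 24.5 ± 0.547 FPKM and Ecscr from 18.2 ± 0.459 to 13 ± 1.54. S1pr1, the receptor of sphingosine 1-phosphate, rose from 2.56 ± 0.171 to 6.85 ± 0.911 FPKM and Flt1, a VEGF receptor gene, from 0.924 ± 0.0677 to 1.96 ± 0.110. Egfl7, Ets1 and Eng did not pass, the counts adjusted over the list alone were also 2 and 2, and the list had no shift (camera adjusted p = 0.824; the sign of its median, -0.06, turned without untreated replicate 3 or BMP4 replicate 1). Of 3 tested lymphatic endothelial genes, Pdpn (podoplanin) fell from 97.4 ± 4.51 to 63.3 ± 2.61 FPKM and Nrp2 rose from 35.3 ± 3.87 to 43.1 ± 2.61, with 1 and 1 also adjusted over the list alone. Vegfc was at 2.88 ± 0.1 and 2.85 ± 0.118 FPKM, and its sign turned without untreated replicate 2 or BMP4 replicate 1. The call of Nrp2 was lost without untreated replicate 1 (limma adjusted p = 0.0619), untreated replicate 2 (0.0747), BMP4 replicate 1 (0.145) or BMP4 replicate 2 (0.133), and with trimmed-mean scaling (0.0592) or rescaling to equal sums (0.0618).

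Genes of the mesenchymal transition list rose more often than they fell. Tnc rose from 17.3 ± 1.26 to 116 ± 4.98 FPKM, the transcription factor gene Snai2 from 38 ± 2.45 to 109 ± 2.89 and Lox, a collagen-crosslinking oxidase gene, from 308 ± 14.8 to 654 ± 10.2. In contrast, Col3a1 fell from 746 ± 4.82 to 197 ± 3.35 FPKM (log2 fold change -1.92, SE 0.04, limma adjusted p = 6.94e-07), and Mmp2 also fell. Of the 20 tested genes 11 rose and 2 fell, or 12 and 2 adjusted over the list alone. The list was shifted upwards (camera adjusted p = 0.00110), with an adjusted p of 0.123 with an estimated correlation. Among 19 tested TGF-beta target genes, 10 rose and 2 fell, or 11 and 2 adjusted over the list alone. The matrix genes Ltbp2, Ctgf and Thbs1 led the rises, with log2 fold changes of 2.12, 2.66 and 1.52, while the receptor gene Tgfbr2 fell from 101 ± 2.85 to 46.8 ± 1.17 FPKM and Cdkn2b fell by 0.28 on the log2 scale. This list was shifted upwards (camera adjusted p = 0.00290), with an adjusted p of 0.168 with an estimated correlation.

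Collagens and matrix-crosslinking enzymes mostly fell. Of 31 tested genes, 19 fell and 7 rose, or 20 and 7 adjusted over the list alone. Besides Col3a1, Loxl2 fell from 80.7 ± 2.07 to 34.8 ± 1.44 FPKM and Col8a1 from 104 ± 3.67 to 51.9 ± 0.857. The list was shifted downwards (camera adjusted p = 0.000117), with an adjusted p of 0.168 with an estimated correlation. The list of fibroblast markers moved the same way, with 8 of 15 fallen and 4 risen, counts that were the same adjusted over the list alone. Dpt and Igf1 fell by 2.55 and 1.88 on the log2 scale, whereas Islr rose from 19.2 ± 1.57 to 77.1 ± 0.718 FPKM, and Gpx3, Pdgfra and Mfap5, named after their values were seen, also rose. It was shifted downwards (camera adjusted p = 0.0313), with an adjusted p of 0.168 with an estimated correlation. All 15 fibroblast genes were listed with values in this line, and the list shares Col3a1 and Col1a1 with the collagen list. Leukocyte markers stayed near their untreated values: Cd68 was at 2.07 ± 0.380 and 2.53 ± 0.409 FPKM, Cd14 at 6.86 ± 1.41 and 6.59 ± 0.863, and Lyz2 at 3.82 ± 0.948 and 3.72 ± 0.357. These 3 did not pass, with 0 of 3 also adjusted over the list alone. Of the 16 genes in that list, 12 were not analysed here. The sign of Cd14 turned without untreated replicate 1 or BMP4 replicate 1, and that of Lyz2 without untreated replicate 1, untreated replicate 3 or BMP4 replicate 3. Of the epithelial marker list, 3 genes had values and 0 reached the mean of 1 FPKM.

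Interferon response genes fell together. Ifit1, an interferon-induced RNA-binding protein gene, fell from 50.8 ± 1.61 to 12 ± 0.687 FPKM, Ifit3 from 96.3 ± 3.29 to 20.2 ± 1.66, the antiviral enzyme gene Rsad2 from 6.85 ± 0.502 to 0.723 ± 0.0665 and the guanylate-binding protein gene Gbp3 from 25.9 ± 0.532 to 7.25 ± 0.473. Their limma adjusted p lay between 1.54e-06 and 2.62e-06. Of 31 tested genes, 29 fell and 0 rose, and the counts adjusted over the list alone were the same. The 2 that did not pass were B2m (log2 fold change -0.18) and Irf1 (-0.77, SE 0.37). The median log2 fold change was -1.24 and the list was shifted downwards (camera adjusted p = 2.96e-23), with an adjusted p of 0.0833 with an estimated correlation. H2-K1 and H2-D1 of this list are close paralogs, so their separate values are uncertain.

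In the inflammatory and NF-kB list, 10 of 17 tested genes fell and 4 rose, with the same counts adjusted over the list alone. Of the 29 genes in that list, 11 were not analysed here. The chemokine gene Ccl2 fell from 74.4 ± 3.09 to 19.0 ± 1.17 FPKM, Cxcl10 from 21.3 ± 1.87 to 3.99 ± 0.248, and complement C3 from 58.0 ± 2.43 to 17.8 ± 0.759. Ptgs2, Cxcl12, Il33 and Csf1, named after their values were seen, rose by log2 fold changes of 1.29, 0.57, 0.55 and 0.23, the call of Csf1 being lost without BMP4 replicate 1 (limma adjusted p = 0.0510). The list was shifted downwards (camera adjusted p = 0.00247), with an adjusted p of 0.168 with an estimated correlation. Genes of the unfolded protein response and amino acid stress also fell, 17 of 26 with 0 risen, or 24 and 0 adjusted over the list alone, and 11 of 26 without untreated replicate 2 or without BMP4 replicate 2. Ddit4, a stress-induced inhibitor of mTOR signalling, fell from 47.9 ± 3.44 to 23.5 ± 0.785 FPKM, the serine synthesis gene Psat1 from 55.5 ± 1.38 to 38.4 ± 0.363, and Sesn2 from 23.9 ± 0.786 to 15.0 ± 0.687. The list was shifted downwards (camera adjusted p = 5.03e-08), with an adjusted p of 0.168 with an estimated correlation.

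Adipocyte genes were the smallest list that passed. Of the 14 genes in that list 8 were not analysed here and 5 were tested, so the result covers only part of it. Fabp4, a fatty acid-binding protein gene, rose from 0.518 ± 0.0379 to 7.45 ± 0.437 FPKM, the transcription factor gene Cebpa from 1.35 ± 0.143 to 4.66 ± 0.472 and Plin4 from 1.61 ± 0.114 to 2.43 ± 0.0744. Lpl was at 60.0 ± 2.12 and 56.2 ± 0.876 FPKM, and Dgat2 was likewise not past the threshold, so that 3 of 5 rose and 0 fell, also adjusted over the list alone. The list was shifted upwards (camera adjusted p = 0.0313), with an adjusted p of 0.168 with an estimated correlation. Chondrocyte genes rose in 4 of 7 cases (Col10a1, Fgfr3, Prg4 and Matn3), with the same 4 and 1 adjusted over the list alone, but 2 of 6 tested without BMP4 replicate 1, where Matn3 did not pass (limma adjusted p = 0.0507). Of the 22 chondrocyte genes in the list, 15 were not analysed here. The deposited list was filtered on the higher group mean, so a gene near 0 in untreated cells could enter it through the BMP4 group alone. Such a gene was Col10a1, the collagen of hypertrophic cartilage, which rose from 0.0174 ± 0.0302 to 2.36 ± 0.234 FPKM. Col11a1 fell from 12.8 ± 1.79 to 8.19 ± 0.900. As a list they did not pass (camera adjusted p = 0.0605), but did with trimmed-mean scaling (0.0490) or without untreated replicate 2 (0.0495) or BMP4 replicate 3 (0.0338); over the alternatives of this list it ranged from 0.0338 to 0.209.

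Smooth muscle and pericyte genes showed 3 rises of 11, Cnn1, Cspg4 and Tagln, and 1 fall, Notch3, or 3 and 2 adjusted over the list alone. Cnn1, which encodes calponin, rose from 5.15 ± 0.352 to 11.1 ± 0.377 FPKM. The call of Notch3 (log2 fold change -0.26) was lost without untreated replicate 2 (limma adjusted p = 0.0616), without BMP4 replicate 3 (0.0507) and with rescaling to equal sums (0.0684), while 2 genes fell without untreated replicate 3. The list did not pass (camera adjusted p = 0.0607) except with a lower filter (0.0350), trimmed-mean scaling (0.0490), quantile normalization (0.0276), without untreated replicate 1 (0.0367) or without BMP4 replicate 2 (0.0408), and ranged from 0.0276 to 0.443 over its alternatives. In the Notch pathway, Hey1 rose and Jag1, a Notch ligand gene, fell from 10 ± 1.12 to 5.41 ± 0.107 FPKM. Of its 12 tested genes 3 rose (Hey1, Lfng and Rbpj) and 4 fell (Dtx4, Jag1, Notch1 and Notch3), or 4 and 4 adjusted over the list alone (camera adjusted p = 0.665). In the WNT list 8 of 21 rose and 4 fell (Wisp1, Frzb, Sfrp4 and Fzd2), also adjusted over the list alone. The receptor gene Fzd4 rose from 6.50 ± 0.719 to 16.4 ± 0.995 FPKM, Sfrp2 from 206 ± 5.41 to 333 ± 27.0, and Wisp1 fell from 43.9 ± 1.62 to 25.4 ± 1.62 (camera adjusted p of the list = 0.242, with a median of 0.03 that turned sign without BMP4 replicate 1 or 2). The call of Fzd2 was lost with any 1 sample left out except untreated replicate 3 (limma adjusted p = 0.0787 to 0.150), and with a pseudocount of 0.1 (0.0507) or 0.01 (0.0515), quantile normalization (0.0553) or rescaling to equal sums (0.0581).

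For retinoic acid genes, 6 of 13 rose and 3 fell (Tgm2, Crabp2 and Aldh1a1), also adjusted over the list alone, and Aldh1a1 did not pass without BMP4 replicate 1 (limma adjusted p = 0.0758) or BMP4 replicate 2 (0.0699). The binding protein gene Crabp2 fell from 2.99 ± 0.350 to 0.468 ± 0.0960 FPKM and the transglutaminase gene Tgm2 from 23.2 ± 0.640 to 7.79 ± 0.591, while the receptor gene Rxra rose from 18.5 ± 0.526 to 23.4 ± 1.32. Rarb had means of 0.259 ± 0.117 and 0.618 ± 0.124 FPKM and lay below the filter. This list had no shift (camera adjusted p = 0.825), and its median of -0.01 and mean of -0.11 differ in sign from the upward direction camera gave. That direction turned without BMP4 replicate 1 (0.95) or BMP4 replicate 2 (0.857). Cell cycle genes rose in 8 of 35 cases, with Mcm4, a replication helicase subunit gene, going from 90.8 ± 1.68 to 123 ± 1.19 FPKM, and Tyms alone fell (log2 fold change -0.29), counts that were the same adjusted over the list alone. Without untreated replicate 2 the number that rose was 4 and without BMP4 replicate 2 it was 5, and without untreated replicate 3 the number that fell was 2. The cell cycle list did not pass (camera adjusted p = 0.0673), except with quantile normalization (0.0191) or without untreated replicate 1 (0.0182), and ranged up to 0.694 over its alternatives. Among CDK inhibitors and growth arrest genes 4 of 20 rose (Cdkn1c, Gas6, Sesn1 and Rbl2) and 8 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.781, with a median of 0.03 and a mean of -0.04; the median turned sign without untreated replicate 1). Cdkn1c rose from 9.12 ± 0.424 to 15.0 ± 0.334 FPKM and Cdkn2c fell from 45.9 ± 2.04 to 35.3 ± 1.21.

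Cholesterol synthesis genes had 8 falls and 0 rises among 21 tested, or 9 and 0 adjusted over the list alone. The falls numbered 5 without untreated replicate 1, 3 without untreated replicate 2, and 2 without BMP4 replicate 1 or BMP4 replicate 2. Mvk, which encodes mevalonate kinase, fell from 21.2 ± 0.888 to 17.2 ± 0.788 FPKM (camera adjusted p of the list = 0.0730). Hypoxia and glycolysis genes went both ways, with 4 of 23 up (Mxi1, Pfkp, Egln3 and Bnip3) and 5 down (Adm, Ndrg1, Ero1l, Tpi1 and Pfkl), or 5 and 6 adjusted over the list alone (camera adjusted p = 0.485). Without BMP4 replicate 1 or BMP4 replicate 2 the number down was 3, as Tpi1 (limma adjusted p = 0.0612 and 0.0565) and Pfkl (0.0625 and 0.0544) no longer passed. Pfkl was also lost without untreated replicate 2 (0.0618) or BMP4 replicate 3 (0.0505), and Bnip3 did not pass with any 1 sample left out (0.0513 to 0.159). The vasodilator peptide gene Adm fell from 8.76 ± 0.651 to 2.02 ± 0.163 FPKM and Mxi1 rose from 10.9 ± 0.119 to 17.1 ± 0.204. Of 17 immediate early and heat shock genes 7 rose and 5 fell (Hspa1b, Atf3, Dusp1, Jund and Hspa1a, of which the Hspa1 paralogs are uncertain), or 9 and 6 adjusted over the list alone (camera adjusted p = 0.424), with Egr1 going from 8.48 ± 0.429 to 15.1 ± 0.221 FPKM. The number that fell was 3 without untreated replicate 2, BMP4 replicate 1 or BMP4 replicate 2, where Jund (limma adjusted p = 0.0653, 0.0777 and 0.0714) and Hspa1a (0.101, 0.0823 and 0.0711) did not pass. Hspa1a was also lost without untreated replicate 1 (0.0715) or BMP4 replicate 3 (0.0927) and with rescaling to equal sums (0.0684). Of 13 mitochondrially encoded genes, mt-Co3 fell from 766 ± 60.2 to 593 ± 58.2 FPKM and 0 passed adjusted over the list alone. The mt-Co3 call was lost without untreated replicate 2 (limma adjusted p = 0.0516), BMP4 replicate 1 (0.0802) or BMP4 replicate 2 (0.0781), and 4 of the 13 fell without untreated replicate 3 (mt-Co3, mt-Nd3, mt-Nd4l and mt-Nd5). The mitochondrial list had a camera adjusted p of 0.0607, which became 0.0490 with trimmed-mean scaling, 0.0167 without untreated replicate 3 and 0.0294 without BMP4 replicate 3, with a range of 0.0167 to 0.727 over its alternatives. In total 9 of 23 tested lists were shifted with the preset correlation, 4 up and 5 down. The other splits of the 6 samples, each of which mixes the treatments in both groups, gave 3 to 6 lists. With an estimated correlation, a setting that also has fewer degrees of freedom, camera called 0 lists, and 4 had an unadjusted p under 0.05. Fry, a rotation test that does not set a list against other genes, called 15 lists as moving on balance one way and 22 as changing in either direction.

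**Figure D2:**
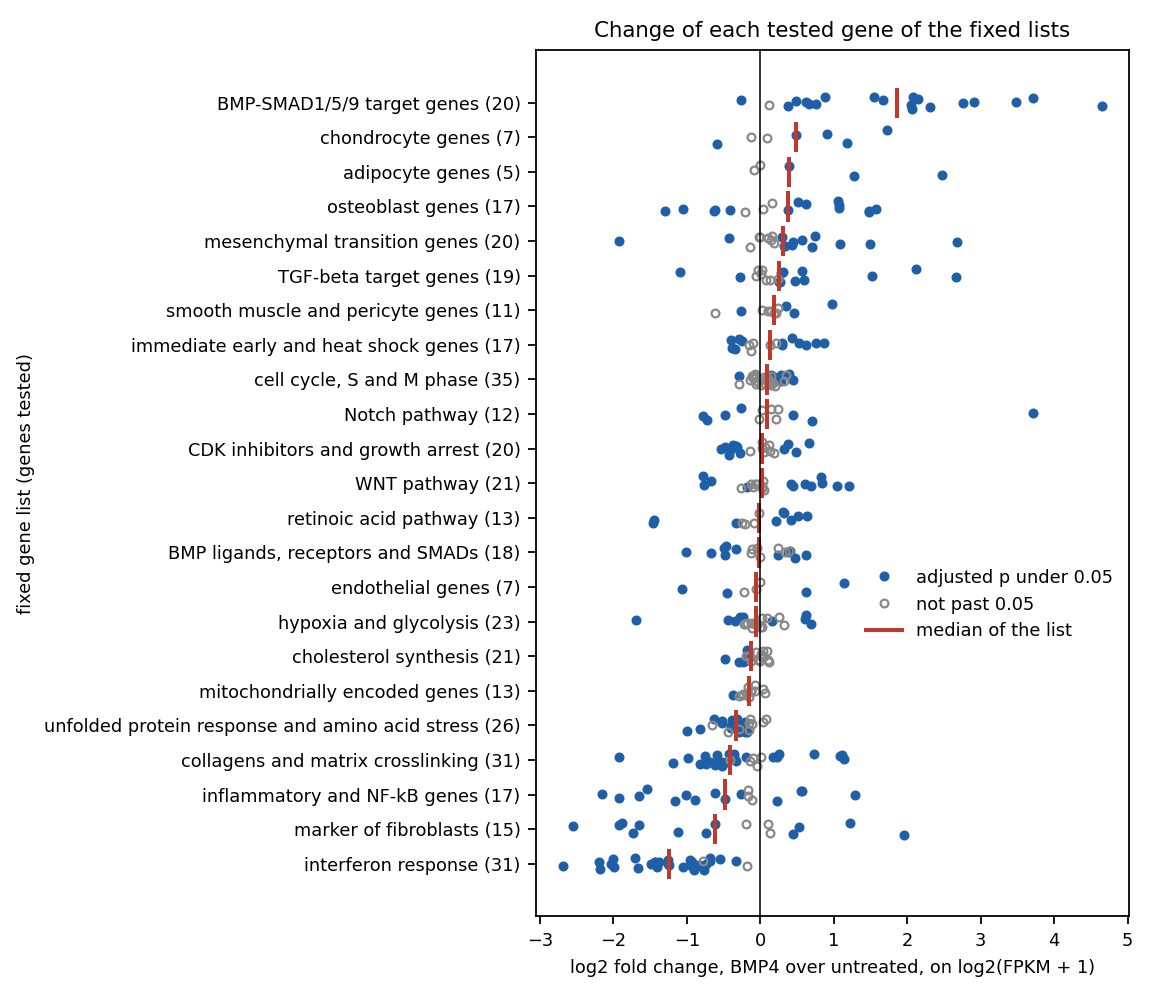
Log2 fold change of each tested gene in the 23 tested lists, BMP4 over untreated on the log2(FPKM + 1) scale, with the number of genes tested in brackets; filled dots passed the limma adjusted p threshold of 0.05, open dots did not, and the red bar is the median of the list. The BMP-SMAD target list has the highest median (1.86) and the interferon response list the lowest (-1.24).

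Values per transcript of the same libraries were compared next. In Lgals9, which encodes the lectin galectin 9, transcript Lgals9-201 fell from 98.7 ± 7.80 to 0.0740 ± 0.0754 FPKM while Lgals9-001 rose from 40.8 ± 7.28 to 83.2 ± 3.65; the pair shares 92.6% of its exonic bases. Of 17213 tested transcripts, 1472 changed by limma's moderated test, 693 higher and 779 lower. The number of transcripts changed by BMP4 was 837 without untreated replicate 2, 774 without BMP4 replicate 1, 739 without BMP4 replicate 2 and 904 without BMP4 replicate 3. Within groups the samples correlated at r = 0.921 to 0.928 across transcripts, less closely than across genes.

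Whether the transcripts of a gene changed unequally was tested in 3871 genes with 10232 transcripts, and 60 genes passed by limma's diffSplice, of which 32 had also changed as genes. Aebp2, a gene of the polycomb machinery (chromosome 6, 140622663 to 140678472), passed with the smallest p. Its transcript Aebp2-003 fell from 10.2 ± 2.40 to 0.172 ± 0.0619 FPKM and Aebp2-002 rose from 0.277 ± 0.0576 to 9.17 ± 0.707, with log2 fold changes of -3.24 (SE 0.19) and 2.99 (SE 0.12). The other 4 tested Aebp2 transcripts, Aebp2-001, Aebp2-004, Aebp2-005 and Aebp2-008, had log2 fold changes of -0.01, -0.03, 0.01 and 0.47 and did not pass. For Lgals9 (chromosome 11, 78962974 to 78984946) the log2 fold changes of Lgals9-201 and Lgals9-001 were -6.54 (SE 0.09) and 1.03 (SE 0.14). In Med25, a subunit gene of the Mediator complex, transcript Med25-006 rose from 1.06 ± 0.140 to 8.46 ± 0.237 FPKM, Med25-002 fell from 3.79 ± 0.111 to 2.36 ± 0.184, and Med25-001, Med25-003 and Med25-014 did not pass, with log2 fold changes of -0.27, 0.26 and 0.08. The diffSplice adjusted p of Aebp2, Lgals9 and Med25 was 4.94e-17, 2.86e-08 and 3.00e-07. With a spread estimated per transcript, a test added after the data were seen, 16 of the 60 genes passed, Aebp2 and Lgals9 among them and Med25 not. The adjusted p of that Simes test (Benjamini-Hochberg, limma on each transcript minus the others of its gene) was 0.0131, 0.000207 and 0.0639 in that order. In simulated data diffSplice called 36 of the unchanged genes, against these 60. Other splits of the 6 samples, which mix the treatments in both groups, called up to 33.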

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

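The test with a spread per transcript was chosen after the data were seen; the other settings were planned, and those meant for read counts were not run because the values are FPKM. The number of changed genes stayed within 1.5 times of 3046 in every setting (2036 to 3317, 1983 to 3046 of them shared with the 3046), and the share higher was between 45.6% and 55.8%, the last with rescaling to equal sums, which moved the median of all genes to 0.03. Leaving out 1 sample gave 985 to 1419 genes higher with BMP4 and 739 to 1079 transcripts changed by BMP4, where fewer samples enter the test. The changed genes with an absolute log2 fold change of at least 1 numbered 191 with a mean of at least 5, where fewer genes are tested. With an estimated inter-gene correlation 0 lists were shifted, with an adjusted p of 0.0833 for BMP-SMAD targets and interferon response, 0.123 for mesenchymal transition and 0.168 for adipocyte, collagen, TGF-beta, inflammatory, unfolded protein response and fibroblast lists. For the adipocyte and mesenchymal transition lists the estimated correlation, -0.229 and -0.0492, lay below the preset 0.01. Their unadjusted camera p still rose, from 0.0120 to 0.0626 and from 0.00024 to 0.016, so correlation between genes does not account for that rise. In this setting camera takes its degrees of freedom from the 6 samples instead of the number of genes, which raises p by itself. For the other lists these values cannot tell how much of the rise comes from correlation. The estimate was 0 or less for 6 lists. Fry called 15 lists directionally and 22 in either direction. Lists that passed only in an alternative were osteoblast (0.0141) and smooth muscle (0.0350) with a mean of at least 0.1; smooth muscle, chondrocyte and mitochondrial (each 0.0490) with trimmed-mean scaling; and smooth muscle (0.0276) and cell cycle (0.0191) with quantile normalization. The cause was not tested. With 1 sample left out, adjusted p ranged from 0.0367 to 0.128 for smooth muscle, 0.0182 to 0.167 for cell cycle, 0.0338 to 0.209 for chondrocyte, 0.0461 to 0.0892 for osteoblast and 0.0167 to 0.163 for mitochondrial genes. The direction camera gave turned, far from the threshold, for retinoic acid genes (0.768 to 0.989) and for BMP ligands and receptors (0.838 to 0.992). Transcript-share genes numbered 112 with a mean of at least 0.1, 16 with a spread per transcript, and 71 to 84 with 1 sample left out. Of 113 named genes tested, 8 lost their call in some setting (Bglap, Fdft1, Kif11, Mvd, Notch3, Nrp2, Tagln and mt-Co3), 3 (mt-Nd3, mt-Nd4l and mt-Nd5) gained one, and 4 uncalled genes changed sign. These were mt-Nd5 (0.0369 with quantile normalization), Lyz2 (0.0219) and Vegfc (0.0201) with rescaling to equal sums, and, with 1 sample left out, Cd14 (-0.135 to 0.0991), Lyz2 (-0.171 to 0.118) and the log2 fold change of Vegfc (-0.0306 to 0.0135).

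No label says that the replicate numbers pair the samples, and same-numbered samples were not more alike than others. Their deviations correlated at -0.149, 0.05 and -0.221, against -0.102 to 0.216 for other pairs. These values cannot tell whether samples were handled in pairs. With the replicate number as a block, which uses up degrees of freedom, 2040 genes, 341 transcripts changed by BMP4 and 31 transcript-share genes passed, and 9 lists were shifted. The depth is unknown, so no limit on low values can be given beyond the spread of the 3 replicates.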

Other observations

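Tests of scaling, of single libraries, of a fibroblast share, of the spread per transcript and of the same pair rule in both sets of genes were chosen after the results were seen. Families of genes whose symbols share their letters before the number, with at least 8 tested members, were compared with all other genes by camera, on a hypothesis that some families move together. Of 173 families 7 passed with the preset correlation, the collagens and Smad genes, most of which are in the fixed lists, and 5 others. Those 5 also overlap the lists in part. Gbp2, Gbp3, Psmb8, Psmb9 and Ifi35 are in the interferon list, and Kif11 and Kif20a are in the cell cycle list. The Gbp, Psmb and Ifi results are therefore not independent of the interferon result. With an estimated correlation the camera adjusted p was 0.923 for each of the 7 families. It was also 0.923 for families far from the threshold with the preset correlation, such as Fbxo (preset camera adjusted p = 0.723). That setting therefore does not tell these families apart and is no evidence against a shift. Guanylate-binding protein genes (Gbp) fell in 9 of 9 cases, with a median log2 fold change of -1.10 (camera adjusted p = 1.25e-06, and adjusted p = 0.923 with an estimated correlation); besides Gbp3, Gbp6 went from 3.55 to 0.932 FPKM and Gbp10 from 1.88 to 0.361, and reads can be shared between these paralogs. Proteasome beta subunit genes (Psmb) fell in 5 of 10 cases (camera adjusted p = 0.00371, and 0.923 with an estimated correlation), namely Psmb4, Psmb7 and the immunoproteasome subunits Psmb10 (log2 fold change -1.52), Psmb8 (-0.93) and Psmb9 (-0.77), of which Psmb8 and Psmb9 are in the interferon list. Interferon-inducible Ifi genes fell in 6 of 9 cases (camera adjusted p = 0.00390, and 0.923 with an estimated correlation), with Ifi44 at -1.23. Psmb4 and Psmb7 did not pass without untreated replicate 2 (limma adjusted p = 0.0627 and 0.0619), BMP4 replicate 1 (0.111 and 0.0827) or BMP4 replicate 2 (0.102 and 0.0836). Genes of the large subunit of the mitochondrial ribosome (Mrpl) fell in 12 of 48 cases with 0 risen (camera adjusted p = 0.00457, and 0.923 with an estimated correlation), with a median of -0.17 over the 48. Genes with Kif symbols, kinesins apart from Kif1bp, rose in 10 of 29 cases with Kif5c fallen (camera adjusted p = 0.0103, and 0.923 with an estimated correlation), led by Kif26b, which went from 0.995 to 6.98 FPKM. Without BMP4 replicate 1 or BMP4 replicate 2 the Mrpl falls numbered 5, and without BMP4 replicate 1 the Kif rises numbered 6. Their medians kept their sign under trimmed-mean, quantile and equal-sum scaling.

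The fall of interferon response genes was weighed against 3 technical explanations. Under the 3 other scalings the median of the list stayed at -1.20 or lower, and after the trend of log2 fold change with exonic length and GC content was removed (31 of 31 genes with a value) it was -1.15, so neither accounts for a median of -1.24. Trimmed-mean and equal-sum scaling apply 1 factor per sample and left the median of all genes at -0.00113 and 0.0349. These 2 scalings could thus move the list only a little. With any 1 library left out at least 27 of the 31 genes fell, against a single deviating library. A biological origin of the lower interferon response in BMP4-treated cells is a hypothesis that none of these checks tested. A difference in culture that ran with the treatment, such as density or an innate response of the untreated cells, was not tested and stays open.

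For the 60 genes with a changed transcript share, the transcripts that moved apart most shared a median of 79.4% of their exonic bases in the 56 genes with annotated pairs, against 66.8% for the most abundant pair of 3343 uncalled genes, a difference of 12.6 percentage points (permutation p = 0.0345, one-sided, 100000 permutations); with the pair that moved apart most in both sets, a choice made later, it was 14.8 points (permutation p = 0.0188). The lower and upper quartiles were 35.8% and 90.2% for called genes, against 34.4% and 89.2% for the most abundant pairs of uncalled genes. For the pairs of uncalled genes that moved apart most they were 31.5% and 88.2%. The sets thus differed at the median but little at the upper quartile, where the pairs are most alike. Reads divided unstably between near-identical transcripts may account for part of the calls, but these values do not settle it. The Lgals9 pair shares 92.6% of its bases, whereas that of Aebp2 shares 31.0%. When the spread was estimated per transcript 16 of the 60 were called again, in line with unequal spread among the transcripts of a gene as a source of calls, although that test also found fewer of the simulated changes. The larger SD within a group was 0.213 of the difference between groups at the median, which decides nothing, since the genes were called on that ratio. Whether BMP4 changes the splicing of Aebp2 or Lgals9 stays open.

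A smaller share of fibroblast-like cells in the BMP4 cultures would, if nothing else changed, lower all markers of that list alike. In fact 4 of them rose past the threshold while 8 fell, so a smaller share alone does not give this mix. The count, known when the test was chosen, cannot tell whether a smaller share lowered the 8 while other markers rose within the cells. The list was fixed beforehand and all 15 of its genes had values in these samples. Dcn and Col1a1 were at 467 and 1059 FPKM in untreated cells. A shift of expression within the cells remains open and was not tested.

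With 3 samples against 3 there are 10 splits, too few for a share under 0.05, and for each count 1 of them, the real one, reached the real value. The real split gave 3046 changed genes and the highest other split 6. For transcripts the values were 1472 and 17, for transcript-share genes 60 and 33, and for shifted lists 9 and 6. Each other split holds samples of both treatments in both groups. Part of the BMP4 effect therefore stays in it, and the rest widens the spread within groups. The counts of the other splits are thus no baseline free of an effect.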
